A study of Gallus gallus with 60 samples.

How the data were processed

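The series holds 60 RNA-seq libraries of chicken (Gallus gallus) utricles, the vestibular sensory organ whose hair cells are replaced after damage. Per the labels' protocols, utricles were dissected, treated with streptomycin, an aminoglycoside antibiotic that kills hair cells, for 24 h and left to recover, and total RNA was taken with Trizol. Libraries were made by Illumina's protocols, per the labels' protocols. The labels give treated and control libraries at 11 time points of 0, 24, 48, 54, 60, 66, 72, 96, 120, 144 and 168 h; they do not say from which moment the hours are counted. They number the biological samples within each arm and time, 2 to 4 per arm. Labels with a decimal after the replicate number were read as a second library of that sample, for replicate 1 at 0 h and replicate 2 at 120 h in both arms; the labels do not spell this out. The labels do not say how many animals or utricles make up a sample, so p-values measure the spread between these samples.

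The authors deposited 1 table of 17684 rows, with a gene name, a description and 1 column per library. The submitters' processing notes name TopHat 1.4.0 and Partek 6.6 without saying what each did; the genome build and annotation are not given in the sources used here, so no coordinates are printed. The unit is not named in the table. The values deposited by the authors were taken as RPKM (reads per kilobase of transcript, scaled to the alignments of the library), because each value times the number of alignments that the table gives for its library fell on whole multiples of 1 step per gene: over 2282 rows checked, 53.2% had more than 90% of their values within 0.05 of a whole step, against 0% without that multiplication. RPKM values are relative: a rise of some transcripts lowers the share of others. Reads shared between near-identical copies could have been split or dropped, and how they were counted is not given, so values of gene families with close copies (ribosomal proteins among them) are less certain. Of the row names, 4080 were Ensembl identifiers; none matched the gene table supplied for assembly GRCg7b, and these rows were tested but not named. 2 columns matched no sample and were not used.

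The count test foreseen for count tables did not apply. Values were transformed to log2(RPKM + 0.5), which understates the fold of low genes. Rows with at least 1 RPKM in at least 2 of the 60 libraries were tested, 13862 in all. Libraries read as repeats of a biological sample were averaged on the log scale, which left 56 samples. The correlation of log values between repeat libraries was 0.984 to 0.993, against a median of 0.952 and at most 0.987 between separate samples of one group. All samples entered 1 linear model with 22 group means, fitted with limma 3.58.1 (empirical Bayes with an intensity trend; statmod 1.5.0, R 4.3.3), which left 34 residual degrees of freedom. Contrasts were the mean treatment effect over the 11 times, over 0 and 24 h, over 48 to 72 h and over 96 to 168 h, each time with equal weight, the effect at each time, and the late minus the early effect (96 to 168 h minus 0 and 24 h). F tests asked whether the treatment effect differed between times and whether control samples differed between times. P-values were adjusted by the Benjamini-Hochberg method over all genes tested and called under 0.05.

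Depth was 1486991 to 40331879 alignments per library (median 21154441). In 7 libraries it was under 5000000, which makes low values there coarse: control replicates 1 and 2 and treated replicate 1 of 24 h, treated replicate 1 of 96 h, control replicate 1 of 120 h, and control and treated replicate 1 of 168 h.

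Samples with the same number in both arms were checked for pairing by the correlation of their deviations from their group means. All 16 pairs at the 5 times with 3 or 4 pairs had r from 0.117 to 0.71. Among them treated replicate 1 of 24 h correlated better with another control than with its own (r = 0.117). Over all 28 pairs r was above 0.1 in 26, the exceptions being both pairs of 60 h (r = 0.075). At times with 2 pairs both have the same r by construction, so they do not count as separate evidence. The numbers were therefore taken to pair treated and control samples. The pairing comes from the shared sample number and this check; the labels do not state it. The main model, fixed before the data were examined, has no block. A model with the 28 pairs as a block (17 residual degrees of freedom) was the alternative, and its value is given as blocked where it changed a call or moved a count by over 1.5 times.

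Before the data were examined, 32 gene lists were fixed, with 1012 entries, of which 825 were in the table and 761 tested. They covered hair bundle and mechanotransduction; hair cell synapse, channels and calcium buffers; hair cell transcription factors; supporting cells; the Notch, FGF, TGF-beta and BMP, and Wnt pathways; DNA replication; mitosis; immediate early genes; p53 targets; endoplasmic reticulum (ER) and integrated stress; heat shock chaperones; interferon response; inflammation; leukocytes; stroma; cartilage and bone; endothelium; erythroid cells; Schwann cells and glia; neurons; melanocytes; muscle; ion-transporting epithelium; mitochondrially encoded genes; nuclear-encoded respiratory chain; cytosolic ribosomal proteins; cholesterol synthesis; cell death and debris clearance; and epithelial repair and cytoskeleton. Some genes stand in more than 1 list. Each list was tested against all other genes with camera (limma) at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry, adjusted over the 32 lists. Each list's count was also taken with p-values adjusted over the list alone.

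The genes named were chosen by a rule fixed before the data were examined: 20 fixed genes (FOS was not among the rows tested, which left 19); the 6 largest rises and 6 largest falls among called genes for all times and for each interval, with the same direction at each of its times (9 of 11 for all times); up to 4 members of each list by smallest p; and the 6 smallest p-values of each F test and of the late minus early contrast. Identifiers, clone names and small RNAs were not named, and some genes that the rule takes are not reported here.

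Alternatives fixed in advance were trimmed-mean scaling (30% of log ratios and 5% of levels trimmed at each end), quantile normalization, no filter (17422 rows), a mean RPKM of at least 1 (12205 rows), pseudocounts of 0.1 and 1, array weights, the replicate block, repeat libraries as separate samples, an added fold threshold of 1 on the log2 scale, and leaving out each replicate number or sample. Where this left 1 sample in an arm, that sample was assumed to vary like the other groups. Steps were tested on simulated data with 200 changed genes among 13862. For all times the model recovered 76.1% of genes changed by 0.5, 98.5% of those changed by 1 and 100% of those changed by 2 on the log2 scale. For 24 h it recovered 9% at 0.5, 40.3% at 1 and 93.9% at 2, and for 144 h, with 2 samples per arm, 1.5%, 16.4% and 74.2%. The simulated noise was normal and independent between genes, with 30% of the variance shared within pairs. At 24 h 95 simulated genes were called, against 1788 in the data. The adjusted threshold was thus stricter in the simulation, and these rates may differ from those in the data.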

Results

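The data are expression values of 60 libraries from chicken utricles, in which streptomycin kills hair cells and supporting cells then give rise to replacements. Treated and control utricles were compared at 11 time points, with 4 biological samples per arm at 24 h, 3 per arm at 72, 96, 120 and 168 h, and 2 per arm at 0, 48, 54, 60, 66 and 144 h. The values were RPKM at a depth of 1486991 to 40331879 alignments per library. Fold changes are log2 differences of log2(RPKM + 0.5), treated minus control, given ± SE from the limma model, and p-values are adjusted over all genes tested unless a list is named. Levels are means ± SD over biological samples. Counts of list members use p-values adjusted over all genes tested; the count adjusted over the list alone is given where it differed. The comparison asked how the transcriptome of the utricle changes while hair cells are lost and replaced.

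Averaged over the 11 times, transcripts of the hair bundle and the hair cell synapse were lower and transcripts of dividing cells higher in treated utricles. Of 25 tested genes of the hair cell synapse, channel and calcium buffer list, 22 fell and 3 did not pass (blocked, 1 rose and 22 fell), with a median of -1.74. OTOF, the otoferlin needed for transmitter release from hair cells, fell by 2.39 ± 0.09 (5.23-fold, adjusted p = 3.43e-23), and the vesicular glutamate transporter SLC17A8 fell by 2.77 ± 0.11 (adjusted p = 5.29e-23). The calcium buffers OCM2 and CALB2 fell by 2.54 ± 0.09 and 2.25 ± 0.13 (adjusted p = 1.51e-24 and 1.56e-17). Of 31 hair bundle genes, 24 fell and 7 did not pass (median -1.18). They included MYO7A (-1.65 ± 0.10, adjusted p = 7.31e-17) and the transduction channel gene TMC2 (-1.93 ± 0.09, adjusted p = 9.25e-20). In the mitosis list 47 of 49 genes rose (48 adjusted over the list alone), with TOP2A at 1.32 ± 0.10 and CCNB2 at 1.37 ± 0.10 (adjusted p = 2.92e-14 and 6.08e-15). In the DNA replication list 33 of 40 rose (37 adjusted over the list alone), with MCM6 at 1.24 ± 0.07 (adjusted p = 3.2e-17). Each of these lists also passed camera with an estimated correlation, with adjusted p of 8.46e-05 for synapse genes, 0.000891 for bundle genes and 0.00444 for both division lists. The largest falls were in SS2 (somatostatin II, -4.70 ± 0.21), NMB (neuromedin B, -3.80 ± 0.15), SKOR2 (-3.62 ± 0.15), SMPX (-3.53 ± 0.18), B3GALT4 (-3.35 ± 0.09) and the tachykinin precursor TAC1 (-3.33 ± 0.18), each lower at all 11 times, with adjusted p of at most 2.06e-18. The largest rises were in EDNRB2, an endothelin receptor, (2.32 ± 0.14), the bHLH gene HES6 (1.97 ± 0.18), ISG12-2 (1.70 ± 0.14), the Notch target HES5 (1.52 ± 0.40), the otoconial protein OTOL1 (1.503 ± 0.24) and CENPF (1.47 ± 0.14), with adjusted p of at most 0.00311.

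Hair cell transcription factors went both ways over all times: 4 of 12 rose and 4 fell (camera adjusted p = 0.21), with a median of 0.062, a mean of -0.125 and a downward camera direction. GFI1 fell by 1.85 ± 0.09 (adjusted p = 5.83e-20), LHX3 by 1.31 ± 0.12 (adjusted p = 2.28e-11) and POU4F3 by 0.77 ± 0.12 (adjusted p = 2.02e-06). ATOH1, the gene that starts hair cell differentiation, rose by 0.66 ± 0.21 (adjusted p = 0.0161), a call that was lost without replicate 1 (adjusted p = 0.166), without replicate 2 (0.24) and with the mean of the stromal markers as a covariate (0.931), a model added after the data were seen. The call of HES5 was lost in the same fits (0.0694, 0.109 and 0.0889). In the interferon list 20 of 28 genes rose (22 adjusted over the list alone), and the list passed with an estimated correlation (adjusted p = 0.0142). Of 16 neuron markers, 2 rose and 7 fell (8 adjusted over the list alone; adjusted p = 0.00583 with an estimated correlation), led by TAC1 and SNAP25 (-1.70 ± 0.10, adjusted p = 2.78e-17). SNAP25 and TAC1 are also made outside neurons. In the cholesterol synthesis list 14 of 18 genes fell, among them FDFT1 (-0.54 ± 0.09) and SQLE (-0.51 ± 0.10) with adjusted p of 9.17e-06 and 8.86e-05. The list had an adjusted p = 0.226 with an estimated correlation and 2.12e-05 with fry. In the list of FGF genes (median 0.065, mean -0.123, camera adjusted p = 0.185 downwards) 1 of 16 rose and 4 fell, with FGF19 at -1.16 ± 0.16 and ETV4 at -0.82 ± 0.10 (adjusted p = 2.19e-07 and 4.41e-09). Of 22 supporting cell markers 10 rose and 2 fell (12 and 2 adjusted over the list alone), with the gap junction gene GJB6 at 1.22 ± 0.15 (adjusted p = 3.38e-08), and of 26 Notch genes 12 rose (15 adjusted over the list alone; blocked, 17 rose and 1 fell), with DLL1 at 1.34 ± 0.16 (adjusted p = 6.51e-09). The lists had an adjusted p of 0.553 and 0.492 with an estimated correlation, and of 0.000135 and 2.24e-05 with fry. In the ER and integrated stress list 5 of 36 rose and 13 fell (7 and 14 adjusted over the list alone), and of 48 ribosomal protein genes 17 fell (18 adjusted over the list alone; blocked 35), with an adjusted p of 0.553 and 0.564 with an estimated correlation. In the Wnt list 11 of 34 rose (13 adjusted over the list alone) and 5 fell, with RSPO3, a secreted Wnt enhancer, at -2.12 ± 0.15 (adjusted p = 5.65e-15).

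Of 28 stromal markers 18 rose over all times (median 0.46). The camera adjusted p of this list was 6.51e-05, but 0.553 with an estimated correlation, and its fry adjusted p was 0.000537. Counts of genes that rose and fell were 11 and 3 of 25 for leukocytes (12 and 3 adjusted over the list alone), 5 and 0 of 13 for cartilage and bone, 0 and 2 of 13 for endothelium (blocked 1 and 2), and 0 and 2 of 8 for erythroid cells. They were 4 and 2 of 12 for Schwann cells and glia (5 and 2 adjusted over the list alone), 3 and 1 of 10 for melanocytes, 1 and 1 of 10 for muscle (blocked 1 and 2), and 1 and 2 of 15 for ion-transporting epithelium. None of these 8 lists had a camera adjusted p under 0.05. With fry leukocytes (adjusted p = 0.00348), cartilage and bone (0.00392) and melanocytes (2.12e-05) passed, and the others did not. For lists of processes the counts of genes that rose and fell were 8 and 5 of 30 for TGF-beta and BMP, 2 and 1 of 19 for immediate early genes (0 and 1 adjusted over the list alone; blocked 5 and 1), 1 and 1 of 19 for p53 targets (blocked 2 and 2), 1 and 2 of 19 for heat shock (blocked 3 and 2), and 5 and 6 of 25 for inflammation. They were 3 and 1 of 46 for the nuclear-encoded respiratory chain (blocked 5 and 3), 8 and 3 of 28 for cell death, and 7 and 3 of 27 for epithelial repair (8 and 3 adjusted over the list alone). None of these 8 lists of processes passed camera. With fry cell death (adjusted p = 0.000114) and epithelial repair (0.0145) passed, and the others did not. Of the mitochondrially encoded genes 3 of 13 fell (blocked 9; camera adjusted p = 0.0189, adjusted p = 0.578 with an estimated correlation and adjusted p = 0.423 after quantile normalization). Among the fixed genes PCNA, MCM2 and CCNA2 rose by 0.44 ± 0.06, 0.81 ± 0.07 and 0.97 ± 0.08 (adjusted p of at most 4.94e-07). JAG1, SOX2, CDKN1A, HSPA5, PTPRC and COL1A1 did not pass over all times (0.17 ± 0.07, 0.06 ± 0.14, 0.02 ± 0.20, -0.13 ± 0.08, 0.10 ± 0.08 and 0.73 ± 0.37). COL1A1 and JAG1 passed in the blocked model (adjusted p = 0.000742 and 0.0403). In all, limma called 4307 of 13862 genes, 2570 higher and 1737 lower. Of these, 449 changed by at least 1 on the log2 scale (106 higher and 343 lower). Under trimmed-mean scaling 48.4% of calls were higher (1956 against 2082 lower), compared with 59.7% as deposited. Without the replicate 2 samples, which left 1 sample per arm at several times, 1781 genes were called.

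**Figure D1:**
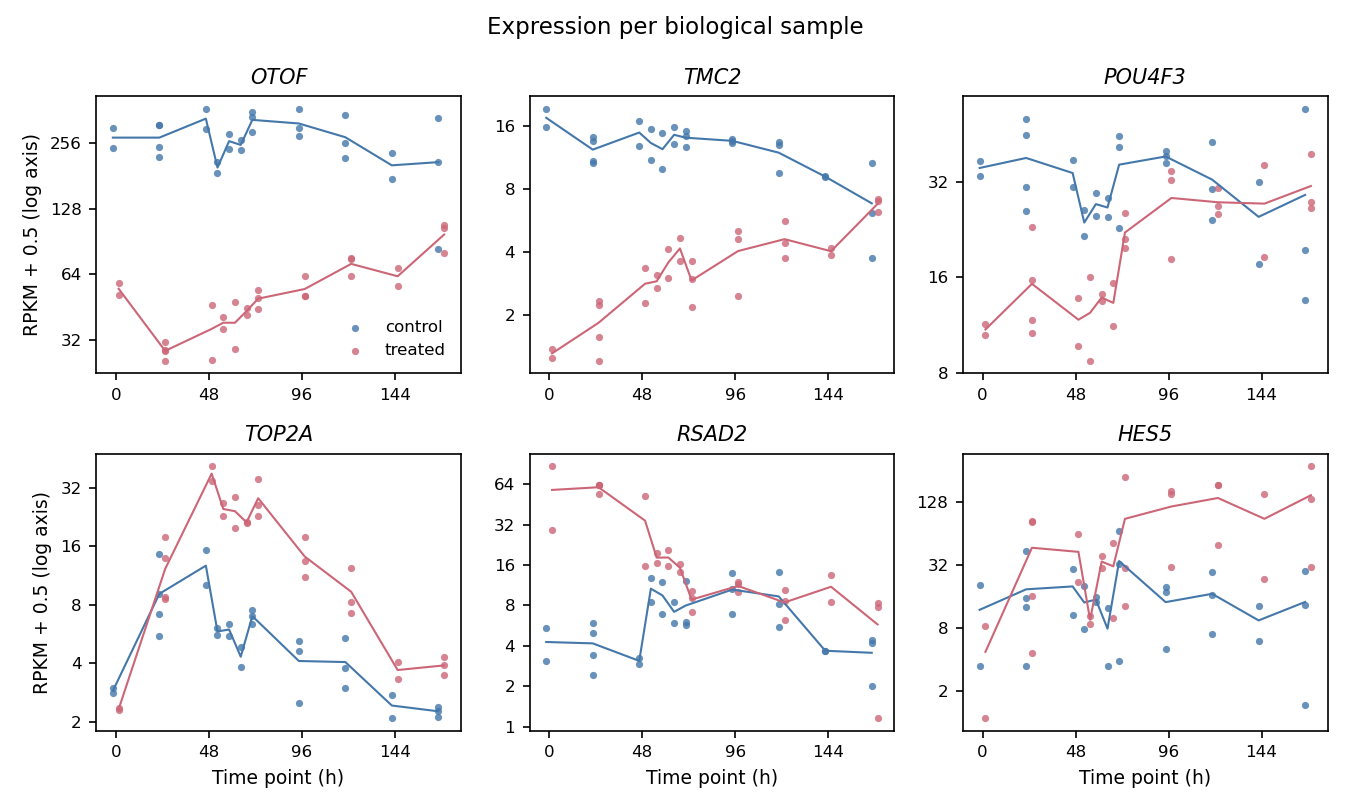
RPKM + 0.5 on a log axis against time point in h for 6 genes, with 1 point per biological sample and a line through the means of control and treated samples. OTOF in treated samples lay at 25.2 to 30.8 RPKM at 24 h and at 79.8 to 107.5 RPKM at 168 h, where 1 of the 3 control samples lay at 83.5 RPKM.

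At 0 and 24 h, transcripts of the hair bundle and the hair cell synapse were already low and interferon response genes were high. Of 31 hair bundle genes 26 fell (median -1.48), and of 25 synapse and channel genes 21 fell and 1 rose (22 and 1 adjusted over the list alone; median -1.54). OTOF measured 271.1 ± 41.2 RPKM (SD, n = 2) in control and 54.5 ± 4.6 in treated samples at 0 h, and 271.1 ± 45.8 (n = 4) against 28.01 ± 2.31 at 24 h. TMC2 measured 16.9 ± 2.5 against 0.819 ± 0.095 RPKM at 0 h (n = 2). Already at 0 h 18 of the 31 bundle genes were lower (median -1.531), which argues against hours counted from the start of the treatment. The largest falls were in B3GALT4 (-4.33 ± 0.21), SS2 (-4.23 ± 0.48), TAC1 (-4.09 ± 0.40), the nicotinic receptor subunit CHRNA9 (-4.06 ± 0.30), OCM2 (-4.05 ± 0.19) and NMB (-3.80 ± 0.33), with adjusted p of at most 1.3e-08. LOXHD1, GRXCR2, MYO7A, CALB2 and SLC17A8 fell by 2.19 ± 0.23, 3.17 ± 0.34, 1.82 ± 0.22, 2.16 ± 0.29 and 3.33 ± 0.24 (adjusted p of at most 5.67e-07). Of 12 hair cell transcription factors 4 fell (blocked, 1 rose and 4 fell), with GFI1 at -1.95 ± 0.20, LHX3 at -1.75 ± 0.27, POU4F3 at -1.51 ± 0.26 and MYT1 at -1.14 ± 0.22 (adjusted p of at most 0.000288), while ATOH1 stood at -0.17 ± 0.48 (adjusted p = 0.876). OTOF and TMC2 fell by 2.77 ± 0.20 and 3.25 ± 0.21 (adjusted p = 3.55e-13 and 1.99e-14). The transcription factor list had an adjusted p = 0.346 with an estimated correlation. Of 16 neuron markers 2 fell (4 adjusted over the list alone; blocked 4; adjusted p = 0.0814 with an estimated correlation).

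Of 28 interferon response genes 19 rose at 0 and 24 h (24 adjusted over the list alone), with a median of 1.26 and an adjusted p = 7.6e-05 with an estimated correlation. The largest rises of all genes were in RSAD2 (3.78 ± 0.37), ISG12-2 (3.65 ± 0.32), PRIC285 (2.69 ± 0.34), CMPK2 (2.66 ± 0.26), the chemokine CCL4 (2.55 ± 0.32) and MX1 (2.52 ± 0.29), with adjusted p of at most 1.53e-07. RSAD2 measured 3.67 ± 1.56 RPKM in control and 60.4 ± 4.6 in treated samples at 24 h (n = 4). The macrophage and leukocyte list had 0 of 25 genes higher and 1 lower (LCP1, -1.20 ± 0.16, adjusted p = 2.72e-07), and the stromal list no limma call among 28 genes (3 at an unadjusted p under 0.05; blocked, 2 higher and 1 lower). Of 40 DNA replication genes 13 rose (20 adjusted over the list alone; blocked 21), with MCM2 at 0.93 ± 0.16 (adjusted p = 5.34e-05, but 0.0581 without replicate 2), though the list had an adjusted p = 0.147 with an estimated correlation. The median of this list was 0.078 at 0 h and 0.849 at 24 h, where 32 members rose. Of 49 mitosis genes 1 rose and 1 fell over both times (blocked 2 and 1); the median was -0.147 at 0 h and 0.382 at 24 h, where 7 rose. The fixed genes SOX2, HES5, JAG1, DLL1, PCNA, CCNA2, TOP2A, CDKN1A, HSPA5, PTPRC and COL1A1 did not pass (-0.11, -0.22, 0.26, 0.23, 0.27, 0.28, 0.07, -0.65, 0.07, -0.25 and 0.08). The muscle list (1 of 10 lower; blocked 2) and the mitochondrially encoded genes passed camera, with an adjusted p of 0.0481 (blocked 0.0529) and 0.00885, but had 0.445 and 0.596 with an estimated correlation. Of the 13 mitochondrially encoded genes limma called none (1 at an unadjusted p under 0.05), and the blocked model called 9 lower. Cholesterol synthesis genes fell in 9 of 18 cases (13 adjusted over the list alone; blocked 14), with INSIG1 at -1.31 ± 0.32 (adjusted p = 0.00353; adjusted p = 0.147 for the list with an estimated correlation). Of 36 genes of the ER and integrated stress list 6 rose and 1 fell (blocked 7 and 2; camera adjusted p = 0.254), with a median of 0.238 at 0 h and -0.012 at 24 h. Its members PHGDH, of serine synthesis, and SLC7A3, an amino acid transporter, rose by 1.70 ± 0.45 and 1.12 ± 0.24 over both times (adjusted p = 0.00796 and 0.00106). At 0 h they stood at 2.80 ± 0.73 and 2.03 ± 0.39 (adjusted p = 0.0248 and 0.00119), and at 24 h at 0.59 ± 0.515 and 0.21 ± 0.28 (adjusted p = 0.498 and 0.694). The limma test called 1768 genes, 939 higher and 829 lower. Of these, 571 changed by at least 1 on the log2 scale (87 higher and 484 lower). The blocked model called 3201, and 3142 were called with repeat libraries as separate samples, which are not independent. The split between higher and lower calls depended on scaling: 53.1% were higher as deposited, 36.3% under trimmed-mean scaling (555 against 975) and 41% after quantile normalization (605 against 869). It also turned without the libraries under 5000000 alignments (586 against 811), an alternative added after the data were seen. Leaving out 1 sample of 0 h turned it for treated replicate 1 (174 against 502), control replicate 1 (482 against 668) and control replicate 2 (513 against 574). It turned as well without control 24 h replicate 2 (775 against 825) or treated 24 h replicate 3 (740 against 786). Without treated 0 h replicate 1, control 0 h replicate 2 or control 0 h replicate 1 the count was 676, 1087 or 1150, and without all samples numbered 2 it was 435.

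At 48 to 72 h, genes of dividing cells were higher in treated utricles and hair bundle and synapse genes lower. All 49 mitosis genes rose (median 1.72), with TOP2A at 2.00 ± 0.15, CCNB2 at 2.01 ± 0.15 and NUSAP1 at 2.16 ± 0.15 (adjusted p of at most 1.81e-13). Of 40 DNA replication genes 34 rose (36 adjusted over the list alone; median 0.92), with MCM6, CDC45, MCM2 and PCNA at 1.53 ± 0.12, 1.86 ± 0.14, 1.25 ± 0.11 and 0.85 ± 0.10 (adjusted p of at most 7.07e-09). Both lists had an adjusted p = 0.000362 with an estimated correlation. TOP2A measured 6.51 ± 0.60 RPKM in control and 27.8 ± 6.6 in treated samples at 72 h (n = 3). The largest rises were in EDNRB2 (2.47 ± 0.22), HES6 (2.36 ± 0.29), CDCA3 (2.22 ± 0.25), SMC2 (2.22 ± 0.18), RRM2 (2.22 ± 0.22) and CENPF (2.21 ± 0.22), with adjusted p of at most 2.55e-08. The Notch ligand DLL1 rose by 1.38 ± 0.25 and LFNG, a modifier of Notch, by 1.02 ± 0.16 (adjusted p = 4.18e-05 and 5.89e-06). Of the Notch list 4 of 26 and of the supporting cell list 6 of 22 rose, while 0 and 2 fell (blocked, 8 Notch genes rose and 1 fell); with an estimated correlation both lists had an adjusted p = 0.703. ATOH1 and HES5 stood at 0.79 ± 0.34 and 0.96 ± 0.63, with an adjusted p of 0.0983 and 0.345 (blocked 0.000246 and 0.0173). CCNA2 rose by 1.301 ± 0.125 (adjusted p = 7.29e-11), and SOX2, JAG1, CDKN1A, HSPA5, PTPRC and COL1A1 did not pass (-0.06, 0.08, 0.12, -0.10, 0.13 and 0.63).

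Hair bundle and synapse genes stayed low at 48 to 72 h: 24 of 31 bundle genes and 22 of 25 synapse and channel genes fell, with medians of -1.32 and -2.06. The largest falls of all genes were in SS2 (-4.92 ± 0.34), SMPX (-4.22 ± 0.29), NMB (-3.94 ± 0.23), SKOR2 (-3.82 ± 0.23), the calcium-binding CIB3 (-3.68 ± 0.18) and CLIC5, a protein of the hair bundle base, (-3.65 ± 0.28), with adjusted p of at most 1.04e-13. OTOF, TMC2, MYO7A and CALB2 fell by 2.74 ± 0.14, 2.09 ± 0.15, 1.88 ± 0.16 and 2.52 ± 0.21 (adjusted p of at most 2.05e-12). Of 12 hair cell transcription factors 2 rose and 4 fell (3 and 4 adjusted over the list alone; median -0.024, camera adjusted p = 0.148). GFI1 fell by 2.24 ± 0.14 and POU4F3 by 1.04 ± 0.19 (adjusted p = 6.24e-16 and 3.92e-05). In the ER and integrated stress list 4 of 36 rose and 12 fell (6 and 16 adjusted over the list alone). The 4 with the smallest p were asparagine synthetase ASNS (-1.87 ± 0.24), PSPH of serine synthesis (-1.60 ± 0.24), the amino acid transporter SLC7A5 (-1.48 ± 0.16) and MTHFD2 of folate metabolism (-1.13 ± 0.16), with adjusted p of at most 1.33e-06; the list had an adjusted p = 0.44 with an estimated correlation. MTHFD2 rose in control samples from 0 to 168 h. Its value can therefore be a difference from rising controls and does not show a fall over time. Of 28 interferon genes 12 rose (13 adjusted over the list alone), with an adjusted p = 0.0832 with an estimated correlation. Of 16 neuron markers 6 fell (1 up and 8 down adjusted over the list alone and in the blocked model; adjusted p = 0.00471 with an estimated correlation), SNAP25 by 2.17 ± 0.16 (adjusted p = 3.76e-14). Of 28 stromal markers 5 rose, with an adjusted p = 0.849 with an estimated correlation. Cholesterol synthesis had 1 of 18 lower (0 adjusted over the list alone; blocked 4; camera adjusted p = 0.114, blocked 0.0354), and ribosomal protein genes no limma call of 48 (1 at an unadjusted p under 0.05; blocked, 3 lower; camera adjusted p = 0.0651, blocked 0.00729). The test called 2677 genes, 1266 higher and 1411 lower. Of these, 694 changed by at least 1 on the log2 scale (212 higher and 482 lower). The split of all calls turned in the blocked model (2089 higher and 1869 lower), with array weights (2165 and 1955 of 4120 genes) and with the stromal covariate (1551 and 1502). It was even without the libraries under 5000000 alignments (1627 each way). Without the replicate 2 samples 831 genes were called.

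**Figure D2:**
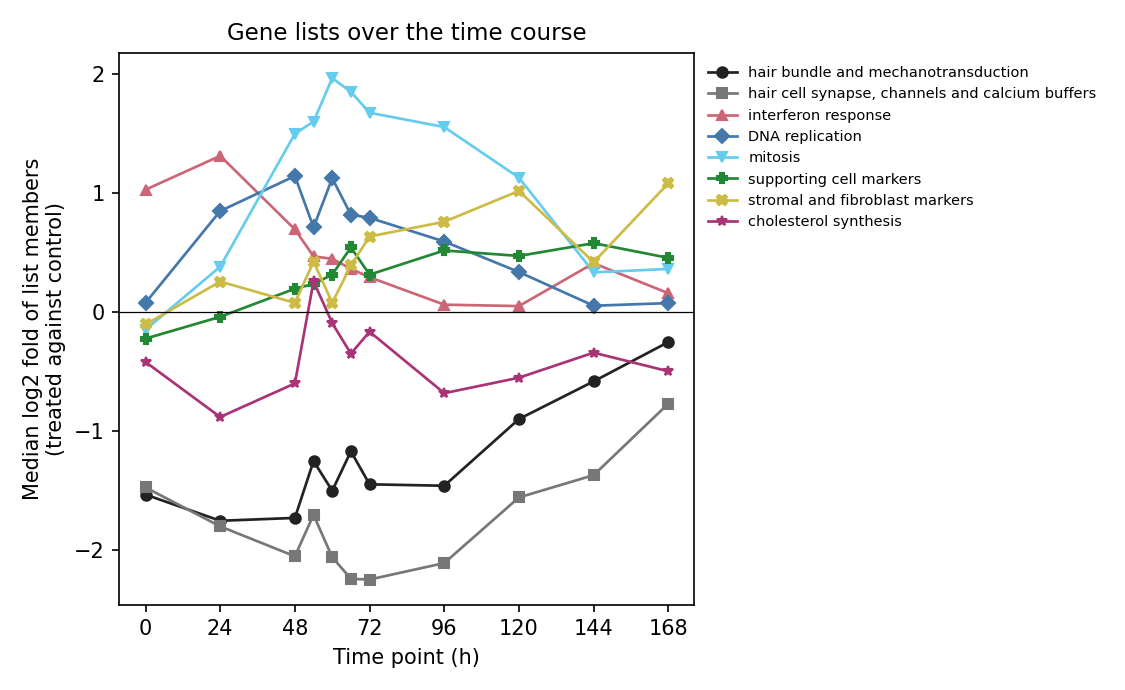
Median log2 fold (treated against control) of the tested members of 8 gene lists against time point in h, with 1 point per time. Hair bundle genes went from -1.53 at 0 h to -0.25 at 168 h, mitosis genes stood highest at 60 h (1.97), and interferon genes were highest at 24 h (1.31).

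At 96 to 168 h, hair bundle and synapse genes were below control on average, and 6 of 26 Notch genes (blocked, 12 rose and 1 fell), 11 of 22 supporting cell markers and 19 of 28 stromal markers rose. With an estimated correlation these 3 lists had an adjusted p of 0.239, 0.142 and 0.165. Of 25 synapse and channel genes 19 fell (median -1.44), and of 31 bundle genes 19 fell and 1 rose (22 and 3 adjusted over the list alone; blocked 21 and 3; median -0.82), with an adjusted p of 0.000596 and 0.0338 under an estimated correlation. At 96, 120, 144 and 168 h the synapse median was -2.106, -1.555, -1.368 and -0.768, with 17, 13, 8 and 4 genes lower (blocked 9 lower and 1 higher at 168 h). The bundle median was -1.457, -0.897, -0.581 and -0.251. Of the bundle genes 20 and 11 were lower at 96 and 120 h, and limma called none at 144 h (13 at an unadjusted p under 0.05; blocked 2 lower). At 168 h 1 bundle gene rose and 1 fell (blocked 1 and 2). OTOF fell by 1.76 ± 0.14, SYN3 by 2.14 ± 0.18, MYO7A by 1.28 ± 0.16 and TMC2 by 1.06 ± 0.15 (adjusted p of at most 1.18e-06). Of 12 hair cell transcription factors 3 rose and 3 fell (4 and 3 adjusted over the list alone; blocked 5 and 4; median 0.182, camera adjusted p = 0.931), and POU4F3 stood at -0.06 ± 0.19 (adjusted p = 0.883). The largest falls were in SS2 (-4.65 ± 0.34), NMB (-3.63 ± 0.23), SKOR2 (-3.51 ± 0.23), SMPX (-3.12 ± 0.29), CIB3 (-3.08 ± 0.18) and NRGN (-3.02 ± 0.38), with adjusted p of at most 1.62e-07. The largest rises were in HES5 (3.09 ± 0.63), EDNRB2 (2.81 ± 0.22), OTOL1 (2.44 ± 0.38), HES6 (2.31 ± 0.29), HES7 (2.07 ± 0.55) and DLL1 (1.86 ± 0.25), with adjusted p of at most 0.00651. HES5 varied widely between samples of one group, from 29.9 to 275.9 RPKM in treated and from 0.97 to 27.4 RPKM in control samples at 168 h. Its call was lost without replicate 2 (adjusted p = 0.0556) and that of HES7 without replicate 1 (0.178) or with the stromal covariate (0.0918). ATOH1 and SOX2 stood at 0.90 ± 0.34 and 0.28 ± 0.22 with an adjusted p of 0.0598 and 0.433 (blocked 0.000109 and 0.00511). GFI1, CALB2 and CCNA2 stood at -1.32 ± 0.14, -1.97 ± 0.21 and 0.89 ± 0.13 (adjusted p of at most 1.25e-06), and JAG1, PCNA, MCM2, CDKN1A, HSPA5 and PTPRC did not pass (0.23, 0.01, 0.21, 0.22, -0.28 and 0.23).

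Of 22 supporting cell markers 11 rose at 96 to 168 h (15 adjusted over the list alone), among them the tectorial protein TECTB (1.19 ± 0.20), OTOA (1.15 ± 0.22) and GJB6 (1.32 ± 0.24), with adjusted p of at most 0.000155. TECTB fell in control samples over the time course, so its value is a difference from falling controls and does not show a rise over time. The count of Notch genes was 10 adjusted over the list alone. In the same samples the count of stromal markers was 22 adjusted over the list alone (median 0.87), with POSTN at 1.10 ± 0.17, FAP at 0.94 ± 0.15 and FBN1 at 0.69 ± 0.12 (adjusted p of at most 7.29e-05). COL1A1 stood at 1.18 ± 0.58 (blocked adjusted p = 0.00125), and ranged from 17.8 to 496.1 RPKM in control and from 189.8 to 1050 RPKM in treated samples at 168 h. The 17.8 RPKM was that of control replicate 3, which had the lowest stromal marker mean of the 168 h samples. With the stromal covariate the Notch list had a camera adjusted p = 0.43, and 4264 genes were called. Of 13 cartilage and bone markers 5 rose (6 adjusted over the list alone) and of 10 melanocyte markers 3 rose (KIT, EDNRB2 and MLPH); with an estimated correlation the adjusted p was 0.191 and 0.0595. Of 25 leukocyte markers 8 rose and 2 fell (12 and 2 adjusted over the list alone; blocked 13 and 2), with LY86 at 0.92 ± 0.16 and GPNMB at -1.55 ± 0.22 (adjusted p = 4.1e-05 and 1.93e-06; adjusted p = 0.235 for the list with an estimated correlation). Of 48 ribosomal protein genes 24 fell (32 adjusted over the list alone; blocked 44; median -0.36, adjusted p = 0.215 with an estimated correlation), with RPL12 at -0.59 ± 0.13. Cholesterol synthesis genes fell in 9 of 18 cases (14 adjusted over the list alone; blocked 15; adjusted p = 0.142 for the list with an estimated correlation). Mitosis genes rose in 42 of 49 cases (43 adjusted over the list alone) and DNA replication genes in 14 of 40, with 1 lower (17 and 1 adjusted over the list alone); their adjusted p was 0.0447 and 0.215 with an estimated correlation. By time, 40 mitosis genes were higher at 96 h, 21 at 120 h and 1 at 168 h. Of the replication genes 11 were higher at 96 h and 3 at 120 h (blocked 19 and 7), and at 168 h 1 rose and 1 fell. At 144 h limma and the blocked model called none of either list (2 mitosis genes and 1 replication gene at an unadjusted p under 0.05). Interferon genes rose in 4 of 28 cases (camera adjusted p = 0.0503), and 2 neuron markers rose and 6 fell of 16 (adjusted p = 0.0757 with an estimated correlation). Shifts of the ER stress (blocked camera adjusted p = 0.0622), heat shock, mitochondrially encoded and respiratory chain lists passed camera but had an adjusted p of 0.548, 0.215, 0.548 and 0.776 with an estimated correlation. The test called 2322 genes, 1337 higher and 985 lower, and 3761 in the blocked model. Of the 2322 genes, 379 changed by at least 1 on the log2 scale (116 higher and 263 lower). The split of all calls turned under trimmed-mean scaling (1124 higher and 1198 lower). It also turned without the replicate 1 samples (548 and 612) or the replicate 2 samples (249 and 329). Without the third control sample of 168 h, whose OTOF value lay among those of treated samples, 2204 genes were called, and without all samples numbered 2 the count was 578.

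The treatment effect differed between times for 205 genes in the F test over all 11 times. That count was 2, 0 and 18 without replicates 1, 2 and 3 (limma; 353 at an unadjusted p under 0.05 without replicate 2). The late minus early count of 1156 became 51, 52 and 264. Late minus early, the hair cell genes OCM2 (2.56 ± 0.24), TMC2 (2.19 ± 0.26) and LOXHD1 (2.19 ± 0.29) moved up, with AMY2A (2.81 ± 0.32), while the interferon genes CMPK2 (-2.72 ± 0.32) and ISG12-2 (-3.09 ± 0.39) moved down, with adjusted p of at most 5.97e-06. OTOF, POU4F3, DLL1 and TOP2A moved up by 1.02 ± 0.25, 1.45 ± 0.32, 1.63 ± 0.43 and 1.04 ± 0.27, and MCM2 moved down (-0.73 ± 0.20; adjusted p from 0.00419 to 0.0171 for the 5 genes). None of these 5 passed without replicate 1 (0.236 to 0.369) or replicate 2 (0.069 to 0.235), which leaves 1 sample per arm at 0 h. ATOH1, GFI1, SOX2, HES5 and CCNA2 did not pass (adjusted p = 0.28, 0.102, 0.593, 0.0526 and 0.0707) but passed in the blocked model (0.00598, 0.0278, 0.0291, 0.000301 and 0.0318). In the F test, OCM2, ISG12-2, ATP8A2, TMC2, PARP14 and CMPK2 had the smallest adjusted p (1.32e-06 to 0.00017). The late minus early contrast called 1156 genes (540 up and 616 down; blocked 2612), and the F test 205 (blocked 578). The late minus early split turned under trimmed-mean scaling (635 up and 538 down) and without the libraries under 5000000 alignments (514 and 414). It also turned without replicate 3 (153 and 111) and without treated 0 h replicate 1 (156 and 101). It was nearly even after quantile normalization (523 and 520), without control 24 h replicate 2 (540 and 539) and without treated 144 h replicate 2 (553 and 547). The late minus early count fell to 257, 604 and 708 without treated 0 h replicate 1, control 0 h replicate 2 and control 0 h replicate 1, and the F test's to 97, 121 and 114, and to 129 without treated 24 h replicate 3. The calls of the intervals overlapped more in falls than in rises. Between 0 and 24 h and 96 to 168 h, 407 lower calls were shared where independent lists would share 58.9, and 107 higher calls where they would share 90.6; 82 genes were called in opposite directions. Between 0 and 24 h and 48 to 72 h, 53 genes were called in opposite directions. Between 48 to 72 h and 96 to 168 h, 642 higher calls were shared against 122.1 for independent lists, and 2 genes were called in opposite directions.

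At single times the counts of genes, higher and lower in treated samples, were 80 and 275 at 0 h, 1039 and 749 at 24 h, 135 and 334 at 48 h, 109 and 250 at 54 h, 175 and 407 at 60 h, 142 and 253 at 66 h, 196 and 400 at 72 h, 256 and 457 at 96 h, 133 and 236 at 120 h, 3 and 69 at 144 h, and 84 and 112 at 168 h. Blocked totals differed by over 1.5 times at 10 of these times: 834 at 0 h, 3302 at 24 h, 615 at 54 h, 1250 at 60 h, 660 at 66 h, 959 at 72 h, 1467 at 96 h, 920 at 120 h, 119 at 144 h and 791 at 168 h. The split turned in the blocked model at 168 h (459 higher and 332 lower), with array weights at 66 h (1092 and 1021) and 96 h (1332 and 1214). Repeat libraries as separate samples, which are not independent, turned it at 0 h (767 and 678) and 120 h (553 and 513). The stromal covariate turned it at 120 h (1059 and 1046). At 24 h it turned without control replicate 2 (627 and 711) or treated replicate 3 (644 and 663). At 168 h it turned without control replicate 1 (140 and 117) or control replicate 2 (285 and 209). At 24 h the median of all genes was 0.126 as deposited and lower by 0.104 under trimmed-mean scaling, and 37.7% of calls were then higher (526 against 871) instead of 58.1%; after quantile normalization 43.4% were (571 against 744). Without the libraries under 5000000 alignments, 743 genes were called at 24 h (236 higher and 507 lower), and at 168 h 97 were higher and 82 lower. At 168 h 31.9% were higher after quantile normalization (68 against 145) instead of 42.9%. OTOF was no longer called at 168 h (-0.90 ± 0.27, adjusted p = 0.0814, blocked 0.0379), where it measured 209.1 ± 125.8 RPKM in control and 97.0 ± 15.0 in treated samples (n = 3). TMC2 measured 6.33 ± 3.47 and 6.28 ± 0.52 RPKM there. Control replicate 3 had the lowest control values, with OTOF at 83.5 RPKM against 208.7 and 335.2 and TMC2 at 3.25 against 5.64 and 10.09 RPKM. Without it OTOF passed (-1.455 ± 0.225, adjusted p = 9.68e-05) and TMC2 stood at -0.25 ± 0.29 (adjusted p = 0.8). Without any other 168 h sample OTOF did not pass (adjusted p from 0.0993 to 0.34); these fits were added after the data were seen. Leaving out 1 sample moved the total by over 1.5 times at 9 times. It became 86, 110 and 189 of 355 at 0 h without control replicate 2, treated replicate 1 and control replicate 1. At 48 h it was 164, 222 and 280 of 469 without treated replicate 1, control replicate 2 and control replicate 1. At 54 h it was 131, 134 and 158 of 359 without treated replicate 1, control replicate 2 and treated replicate 2. At 60 h it was 188, 226, 278 and 1156 of 582 without treated replicate 2, control replicate 2, control replicate 3 and treated replicate 3. At 66 h it was 156, 184 and 207 of 395 without control replicate 2, treated replicate 2 and treated replicate 1. It was 373 of 713 at 96 h without control replicate 3 and 183 of 369 at 120 h without treated replicate 2. At 144 h it was 18, 23, 26 and 29 of 72 without treated replicate 2, control replicate 1, treated replicate 1 and control replicate 2. At 168 h it was 494 and 74 of 196 without control replicate 2 and treated replicate 1.

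**Figure D3:**
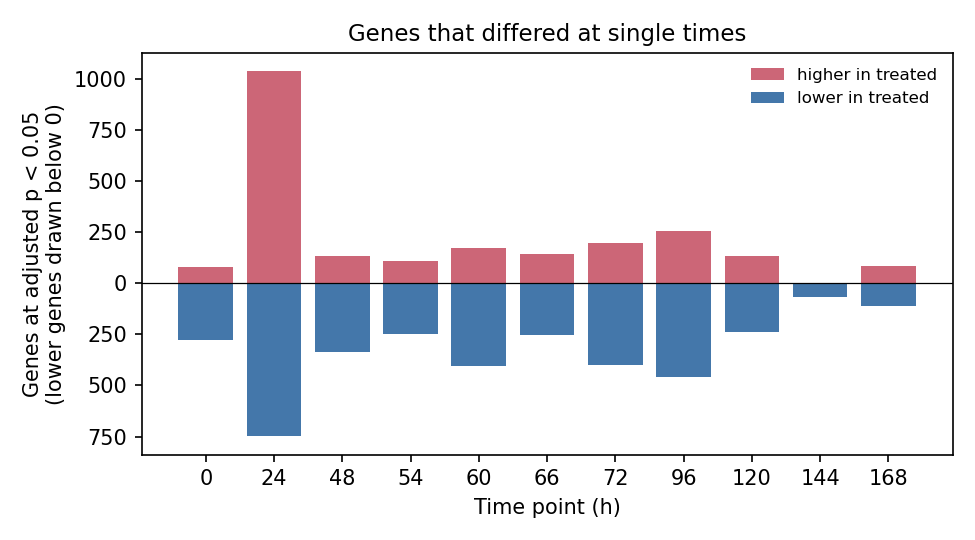
Number of genes at adjusted p < 0.05 at each time point in h, higher in treated samples above 0 and lower in treated samples below 0. The tallest bars are those of 24 h (1039 and 749), the time with the most samples, and the shortest those of 144 h (3 and 69).

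Control utricles also changed over the 11 times, with 896 genes called by the F test. TECTB, the structural protein of the overlying membranes, went from 218.5 ± 8.6 RPKM at 0 h (n = 2) to 12.9 ± 8.3 at 168 h (n = 3), and the malic enzyme ME1 from 279 ± 45 to 72.4 ± 17.4. WIPI1, an autophagy gene, went from 39.2 ± 3.6 to 140.1 ± 7.3, MTHFD2 from 16.3 ± 1.1 to 158.8 ± 23.3, the transcription factor CREB3L1 from 2.92 ± 0.86 to 35.4 ± 4.2, and PHGDH from 0.675 ± 0.038 to 132.4 ± 80.4 RPKM. These 6 genes had the smallest p of the F test (adjusted p from 6.34e-10 to 4.1e-09). Among the fixed genes TOP2A, CCNA2, HSPA5, PCNA, MCM2 and TMC2 also differed between times in control samples (adjusted p = 2.91e-06, 4.19e-06, 0.00797, 0.0265, 0.032 and 0.0407). At 168 h control replicate 3 stood apart from replicates 1 and 2 for HSPA5 (856.1 RPKM against 241.9 and 280.1), PHGDH (225.3 against 86.4 and 85.5) and TECTB (3.90 against 20.3 and 14.5). It also had the lowest TMC2 value (3.25 against 5.64 and 10.09), though replicates 1 and 2 differed widely from each other too. In fits added after the data were seen, TMC2 did not pass without control replicate 3 (adjusted p = 0.218), while HSPA5, PHGDH and TECTB did (0.00308, 1.63e-08 and 2.85e-10). The call of TMC2 was also lost without control replicate 1 or 2 of 0 h (0.0684 and 0.094), replicate 1 of 24, 48, 66 or 168 h (0.0522, 0.0632, 0.0552 and 0.132), replicate 3 of 72 h (0.056), any replicate of 96 h (0.0511 to 0.053) or either of 144 h (0.0613 and 0.0569). That of MCM2 was lost without control replicate 1 of 0, 24, 48 or 66 h (0.0549, 0.125, 0.0578 and 0.0551), replicate 3 of 24 h (0.102) or replicate 2 of 66 h (0.0512). That of PCNA was lost without control replicate 1 of 0 h (0.0591) or replicate 1 or 2 of 24 h (0.0744 and 0.0996). Without control 0 h replicate 1 the F test called 587 genes, and without all samples numbered 1, 2 or 3 it called 133, 35 or 411.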

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

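The tests of hair cell transcripts in 1 control sample, of the interferon genes and of the smaller late deficit were chosen after the results were seen, except that of a treated sample under a control label; the comparisons with other splits of the samples were planned.

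2 samples lay far from the others of their group. In control replicate 4 of 24 h CALB2 measured 343.9 RPKM against 646 to 677.6 in the other 3 samples (gap 0.905 of the range), and in control replicate 3 of 24 h the interferon list had a mean log2 value of 3.348 against 3.108 to 3.12 (gap 0.952 of the range). Both gaps exceed Dixon's 95% critical value for 4 samples. The test was run on 46 combinations of group and measure, of which chance puts about 1 in 20 past that value.

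The treatment effect differed between times for 205 genes in the limma F test. Late minus early, OTOF differed by 1.02, POU4F3 by 1.45, TMC2 by 2.19, DLL1 by 1.63, MCM2 by -0.73 and TOP2A by 1.04 on the log2 scale. Among lists the median differed upwards for hair bundle (0.625), synapse and channels (0.362), hair cell transcription factors (0.54), supporting cells (0.73), mitosis (0.778), Wnt (0.19), leukocytes (0.361), stroma (0.812), cartilage and bone (0.676) and melanocytes (0.774). It differed downwards for ER stress (-0.305), heat shock (-0.363), interferon (-0.872) and ribosomal proteins (-0.315). With an estimated correlation only the bundle, interferon and melanocyte lists passed (adjusted p = 0.0458, 0.00135 and 0.0458) among these 14.

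In the third control sample of 168 h OTOF stood among treated samples, at 83.5 RPKM against 208.7 and 335.2 in the other controls. TMC2 and POU4F3 lay below all 3 treated samples there (3.25 against 5.69 to 6.65 RPKM and 13.1 against 25.9 to 38.5 RPKM). They did so in control replicate 1 of 168 h as well (5.642 and 19.03 RPKM), so this was not particular to the third control sample. A swap with a treated sample needs a partner, but the highest treated OTOF of 168 h was 107.5 RPKM. A treated sample under a control label would raise the 119 genes that were higher in treated samples at 96 to 144 h; their median difference from the other controls was -0.545, against 0.664 to 0.77 in treated samples, and that of the 298 lower genes was -0.692, against -1.233 to -0.93. The ER stress list had its highest mean of the 168 h samples here (6.466 against 5.602 to 5.974), with HSPA5 at 856.1 RPKM against 224.8 to 280.1, which is consistent with a stressed sample. Whether stress lowered the hair cell transcripts stays open. This sample also had the lowest stromal marker mean of the 168 h samples (2.377 against 3.39 to 4.557 on the log2 scale). Stromal markers rose in late treated samples, so low stroma could lower the 119 genes whatever the label, which was not tested. The 119 genes alone therefore cannot exclude a treated sample poor in stroma.

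Interferon genes were higher in treated samples at 0 and 24 h (median 1.26), in 6 of 6 pairs. Leukocyte markers had a median of 0.107 (SD 0.427 over members; the camera direction was downwards, adjusted p = 0.806), with CTSS at 0.35, CD74 at -0.15, CD3E at -0.40, GPNMB at -0.11 and LAPTM5 at 0.11, which argues against a matching rise in leukocytes. The interferon median was 1.102 without libraries under 5000000 alignments and 1.178 under trimmed-mean scaling, so neither low depth nor scaling is its whole cause. A response of cells already in the utricle to treatment may remain as a hypothesis, and it was not tested.

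The deficit of 56 hair bundle and synapse genes was smaller at 96 to 168 h than at 0 and 24 h (median late minus early 0.543), but with an estimated correlation the shift passed for bundle genes (adjusted p = 0.0458) and not for synapse and channel genes (adjusted p = 0.208), whose median was -2.106 at 96 h against -1.471 at 0 h and -1.798 at 24 h. From 24 to 168 h these genes moved by a median of 0.905 in treated samples (50 of 56 higher) and -0.485 in controls (7 of 56 higher, -0.182 without the third control sample). This argues against a fall in controls alone between 24 and 168 h. Between these times the control median fell as well, so the narrowing includes a fall in controls, smaller without the third control sample. The size of its share was not tested, nor was the change from 0 h. The late minus early median was 0.486 without that control sample and 0.516 with the stromal covariate, so neither is its whole cause. Regrowth of hair cells may be a candidate explanation, as may rising transcription in surviving ones; these were not told apart by any test here.

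Other splits of the treated and control samples within times were compared with the real one. Of 100 splits, only the real one reached its count for all times (4307, highest other 1360) and for 0 and 24 h (1768, 122). The same held for 48 to 72 h (2677, 526), for 96 to 168 h (2322, 652), and for 24 h with 35 splits (1788, 454). Each share is under 0.05, so such counts are unlikely from a chance split of the samples. At 24 h only 7 other splits part as many pairs as the real one, too few for a share under 0.05 among these. Among splits that part as many pairs as the real one, the highest counts were 0, 108, 278, 0 and 30; the others part fewer pairs, so that differences between pairs enter them. At 72, 96, 120 and 168 h the 10 splits are too few for a share under 0.05, with 596, 713, 369 and 196 genes and highest others of 2, 0, 2 and 461. At 168 h 5 of 10 splits gave as many, and the highest set control replicates 1 and 3 with treated replicate 1 against the rest, which keeps pairs 1 and 2 whole and parts pair 3, so differences between pairs enter it; splits that part as many pairs as the real one gave at most 2, and the blocked model called 791. When times were permuted over whole pairs, 1 of 100 draws (the real one) reached 205 genes for the F test of the treatment effect (highest other 4) and 1156 for late minus early (5), and 2 of 100 reached 896 for control samples over time, the other with 1022, a share of under 0.05.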

How the results depend on the processing

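The settings without libraries under 5000000 alignments, without the third control sample of 168 h, without each sample in turn for the counts over all times and intervals and for named genes at 168 h and in control samples over time, and with the stromal covariate were chosen after the data were seen; the others were planned. Of the counts under other settings 216 stayed within 1.5 times and 85 moved further. For these 85 the cause was not tested, apart from effects by construction. Such effects come from fewer samples, a stricter threshold, or repeat libraries counted as independent samples, which raises counts. Quantile normalization gave 112 genes at 144 h. Array weights, whose estimation stopped short of its convergence tolerance, gave 4120 at 48 to 72 h, 773 at 0 h, 761 at 48 h, 1447 at 54 h, 2113 at 66 h, 2546 at 96 h, 37 at 168 h, 322 for the F test of the treatment effect and 1843 for controls over time. The replicate block gave 3201 at 0 and 24 h, 3761 at 96 to 168 h, 2612 for late minus early, 834 at 0 h, 3302 at 24 h, 615 at 54 h, 1250 at 60 h, 660 at 66 h, 959 at 72 h, 1467 at 96 h, 920 at 120 h, 119 at 144 h, 791 at 168 h and 578 for the F test; beyond the calls given as blocked in the results, it changed no other call of a fixed gene or list over all times, in an interval or late minus early. Repeat libraries as separate samples gave 3142 at 0 and 24 h, 2219 for late minus early, 1445 at 0 h, 1066 at 120 h, 568 for the F test and 1905 for controls over time. A log2 fold of at least 1 left 449 for all times and 571, 694 and 379 for the intervals. It left 513 for late minus early (303 up and 210 down) and 736 at 24 h (216 higher and 520 lower). Without libraries under 5000000 alignments there were 585 at 0 h, 743 at 24 h and 114 at 144 h. The stromal covariate gave 4264 at 96 to 168 h, 2734 at 24 h, 1228 at 96 h, 2105 at 120 h and 1357 at 168 h, and turned the direction of the stromal list itself (camera adjusted p = 0.774 for all times, 0.925 at 48 to 72 h and 0.903 at 96 to 168 h), which follows from its construction.

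Leaving out 1 replicate number gave 1781 to 4300 genes for all times, 435 to 1839 at 0 and 24 h, 831 to 2683 at 48 to 72 h, 578 to 2306 at 96 to 168 h, 51 to 1262 for late minus early, 0 to 199 for the F test of the treatment effect (limma; 353 at an unadjusted p under 0.05 where it was 0) and 35 to 950 for controls over time. Leaving out 1 sample gave 86 to 326 at 0 h, 1248 to 2001 at 24 h, 164 to 417 at 48 h, 131 to 245 at 54 h, 188 to 1156 at 60 h, 156 to 311 at 66 h, 458 to 536 at 72 h, 373 to 680 at 96 h, 183 to 337 at 120 h, 18 to 29 at 144 h and 74 to 494 at 168 h. An arm left with 1 sample was assumed to vary like the other groups. Over all settings 2650 list results counted as kept, 55 as gained, 108 as lost and 3 as turned. For genes 2523 counted as kept, 31 as gained and 47 as lost. A result that did not pass in the main fit counted as kept whenever its direction changed. The estimated correlation and fry were compared by adjusted p alone, without direction. By that count fry gained 14 list results and lost 9, and the estimated correlation lost 43. The 7 libraries under 5000000 alignments limit what can be seen of low genes at 24, 96, 120 and 168 h.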

Other observations

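The test of hair bundle against synapse genes was chosen after the values were seen. Over the 11 late pairs (96 to 168 h) the mean log2 difference of hair bundle genes lay above that of synapse and channel genes in 11 of 11 pairs, by 0.445 ± 0.143 (SD). The two-sided exact sign-flip permutation p was 0.0009766, the smallest that 2048 sign assignments can give. In the 6 early pairs the difference was 0.211 ± 0.23 (SD), with bundle genes above in 5 of 6. Late and early pairs differed by 0.233 (two-sided exact permutation p = 0.01543). The test left out 48 to 72 h. The mean log2 fold of the bundle and synapse lists was -1.555 and -1.702 at 0 and 24 h. It was -1.293 and -1.851 at 48 to 72 h, and -0.733 and -1.182 at 96 to 168 h. The gap was thus present before 96 h, when the bundle mean had moved towards control and the synapse mean away from it. The difference between late and early pairs holds both movements. By itself it cannot show that bundle genes return towards control ahead of synapse genes. It was found and tested on the same samples. The lists also differ in their starting levels, which was not tested.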
